A study of Mus musculus with 6 samples.

How the data were processed

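Gene expression was measured by RNA sequencing in 6 libraries of cultured cells labelled mouse articular chondrocytes, 3 untreated and 3 after fluid shear stress. Per the labels' protocols, cells came from 3-week-old male mice and were used at passage 1 to 3, total RNA with an integrity number of at least 7 went into library preparation with 15 PCR cycles, and libraries were sequenced on an Illumina HiSeq. No unique molecular identifiers are mentioned, so counts are of reads. How the untreated cells were handled during the 2 h of flow (chamber, medium, serum) is not given in the sources used here, nor is any batch, date or pairing. Groups were taken from the treatment label and replicate numbers from the sample titles.

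The deposited count table holds whole-number read counts per gene symbol for 21878 genes, not normalised, in 1 column per library. The deposited FPKM table gives the same genes and libraries as fragments or reads scaled to gene length and library size. Per the submitters' processing notes the genome build was mm10 and the tools were HISAT2 2.1.0, HTSeq and Cufflinks, with no role, order or other version stated. The annotation, the counting strand and any filter are not given in the sources used here. The authors' FPKM values equalled the count divided by the library total and by a fixed gene length, with a largest relative deviation of 3.1e-14, so they hold no information beyond counts and lengths. Counts of reads shared between paralogs or overlapping genes depend on the authors' counting and were used as deposited. No line of the table named anything other than a gene, 5190 genes had 0 counts in all libraries, and 0 columns of per-sample values were left without a sample. Gene symbols and NCBI gene identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names, for 99.3% of genes, and coordinates come from it. The GC content of a gene was that of its longest GENCODE transcript (release M21), and its length was the one implied by counts and FPKM.

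Total counts per library ran from 19622134 to 21682897. The biological coefficient of variation was 12.1%. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3; robust dispersion estimate and robust glmQLFit, glmQLFTest, 2-sided) with TMM factors, the filterByExpr filter (13001 genes kept), group as the only term, and Benjamini-Hochberg adjustment at 0.05. Normalised expression is in CPM from TMM-scaled library sizes, as mean ± SD of 3 libraries. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The gene lists, the rule for naming genes and all settings not called added below were fixed before the data were examined. In the 31 gene lists, 496 of 512 symbols were found. The mitochondrially encoded mRNAs had 0 symbols in the table and were not analysed here, and no erythroid marker passed the main filter. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1; log2 CPM with a prior count of 2, preset correlation 0.01, variance trend, adjustment over the 25 lists), with camera using an estimated correlation, and with fry.

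The genes to be named were the 10 largest rises and the 10 largest falls among genes that passed the test, had a mean of at least 5 CPM and did not overlap between the groups, leaving out predicted genes. Added to these were up to 4 members of each list with the smallest p (1 where a list had no call), and Sox9, Col2a1, Acan, Mmp13, Adamts5, Piezo1 and Trpv4. The rule gave 130 genes, all of which are reported. The 12 genes named outside it are Fos, Amotl2, Cenpf, Lyz2, Cd68, Ptprc, Adgre1, Klf15, Klhl24, Irs2, Cat and Dusp6, all after their values were seen.

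The alternatives were RLE factors, upper-quartile factors and library totals; no filter, and at least 1 CPM in 3 libraries; DESeq2 1.42.0 on genes with at least 1 count; limma-voom; limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, and on log2(FPKM + 1) without that filter; the replicate number as a block; and each library left out in turn. Fold changes on the log2(FPKM + 1) scale understate those of low genes. Added after the data were seen were offsets that removed each library's trend of log2 CPM on transcript GC content and length (natural splines with 4 degrees of freedom each; 99.6% of tested genes had both), 4 further gene lists, and gene ontology terms of the count table with at least 15 tested genes and an upper limit on size. All 10 splits of the libraries into 3 and 3 were refitted. The spread of a list median was the SD over 1000 bootstrap draws of its members.

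The steps were tested on simulated data. Counts for the 13001 genes were drawn from the libraries' means and sizes for the comparison of shear with control, with 200 genes changed. The main test recovered 71.6% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, with 3 false calls among 175, and made 0 calls when no gene was changed. The simulated genes were independent, and their spread between libraries was set by expression level alone. No GC trend or outlying library was simulated, so these rates need not hold for the real libraries.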

Results

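RNA sequencing measured gene expression in cells labelled primary chondrocytes, the cells that make and maintain cartilage. They were taken from the joints of young male C57BL/6 mice and grown in culture. The 6 libraries formed 2 groups of 3. Control cells were untreated, and shear cells were exposed to a fluid shear stress of 20 dyne/cm2 for 2 h in a parallel-plate chamber, in which medium flowing over a culture slip drags on the cells. Total gene counts were 21204187, 21682897 and 21153336 in control replicates 1 to 3 and 20300986, 19622134 and 19750667 in shear replicates 1 to 3. The replicates are called biological, and nothing used here says whether they came from separate animals, so the p-values measure the spread between these libraries. Every pair of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 7.15 to 13.7 among controls and 9.41 between shear replicates 1 and 2. Shear replicate 3 stood apart from shear replicates 1 and 2, at 42.0 and 29.1, while pairs across the groups lay between 44.1 and 64.4.

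The comparison asked which genes differ in expression after 2 h of shear. Of the 13001 genes tested, 3957 were changed between control and shear, 2102 higher and 1855 lower after shear. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at an adjusted p of 0.05 or less. How control cells were handled during the 2 h (chamber, medium, serum) is not given. Effects of shear and of such handling therefore cannot be told apart. The largest rises were ranked among called genes with at least 5 CPM and no overlap between the groups, predicted genes left out. They included the early-induced transcription factors Egr3, Fosb, Nr4a1, Nr4a2 and Nr4a3. Of 15 listed circadian clock genes 11 rose, and of 25 listed cell cycle genes 17 fell (camera adjusted p = 1.06e-06 and 0.000103 for the lists, and adjusted p = 0.106 and 0.689 with an estimated correlation). CPM values are counts scaled to library size, as mean ± SD with n = 3 in each group. Adamts5, a protease that cleaves the cartilage proteoglycan aggrecan, rose from 183 ± 13.3 to 425 ± 27.2 CPM. Sox9, the transcription factor that directs the chondrocyte programme, fell from 38.5 ± 3.78 to 29.8 ± 0.367 CPM. The Sox9 call was lost without control replicate 1, control replicate 2 or shear replicate 2. Its log2 fold change was then -0.338, -0.317 and -0.375, against -0.371 with all libraries. A fit that leaves out 1 library has fewer samples, so here and below a call can be lost with little change in its size. In controls Col2a1 and Acan, which encode the main cartilage collagen and aggrecan, stood at 78.0 and 15.2 CPM. Col1a1, the collagen of fibroblasts and bone, stood at 10417 CPM in controls. The macrophage gene Lyz2 was also far above Col2a1. Given Lyz2, some changes may come from cells other than chondrocytes, and which cells they came from was not tested. The levels of Col1a1 and Col2a1 alone do not tell other cells from cultured chondrocytes.

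At least 2-fold changes were found in 528 genes, 378 higher and 150 lower. The 3 shear libraries and the 3 control libraries did not overlap in 6365 genes, 49.0% of those tested, where chance gives 10%. The median log2 fold change of all tested genes was -0.00. Calls followed base composition. In the lowest of 4 equal bins of transcript GC content (median 42.1%), 1202 genes were higher and 131 lower, and in the highest (57.2%), 197 were higher and 667 lower. The count of changed genes was 2127 without control replicate 1, 2578 without control replicate 3 and 2285 without shear replicate 2, and that of genes changed at least 2-fold was 345 without control replicate 1 and 150 in limma on log2(FPKM + 1). After each library's trend with GC content and transcript length was removed, a check added after the data were seen, 3387 genes were called, and 2497 of the 3957 were called again in the same direction.

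**Figure D1:**
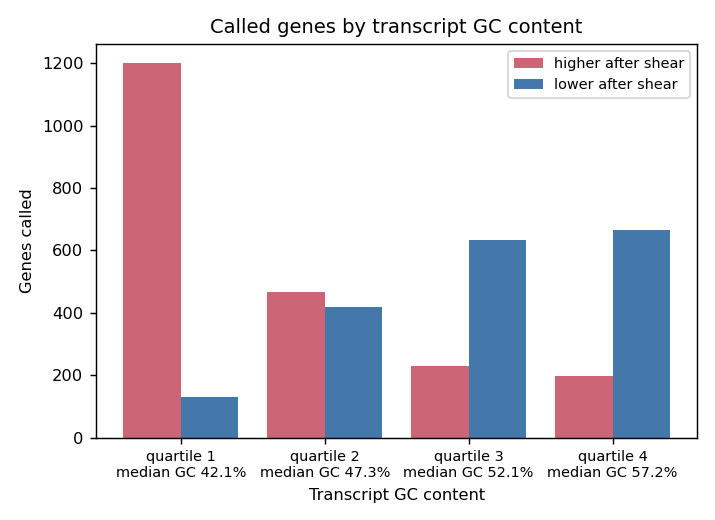
Genes called higher (red) or lower (blue) after shear, counted in 4 equal bins of the tested genes ordered by transcript GC content (x axis, with the median GC content of each bin; y axis, number of genes). The lowest bin held 1202 higher and 131 lower genes, and the highest held 197 higher and 667 lower.

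Egr3, a zinc-finger transcription factor on chromosome 14 (70077317 to 70082613, mm10), rose most among called genes with at least 5 CPM and no overlap between the groups, predicted genes left out, from 8.13 ± 1.47 to 101 ± 7.62 CPM (log2 fold change 3.63 ± 0.13 SE, adjusted p = 2.96e-05 by edgeR's quasi-likelihood test). The orphan nuclear receptors Nr4a1, Nr4a3 and Nr4a2 rose by 3.15 ± 0.51, 2.78 ± 0.43 and 2.40 ± 0.37 on the log2 scale. Klf11, a Krüppel-like repressor, rose by 2.82 ± 0.20, the arrestin-domain gene Arrdc3 by 2.77 ± 0.23, Rasl11b by 2.54 ± 0.23 and the pro-apoptotic BH3-only gene Bmf by 2.50 ± 0.40. Fosb, an AP-1 subunit, rose by 3.36 ± 0.71 and Edn1, which encodes the peptide endothelin-1, by 2.57 ± 0.55. Their calls were lost without control replicate 1 (edgeR adjusted p = 0.0622 and 0.0652) or control replicate 2 (0.0653 and 0.0671), and with no filter on low counts (0.0519 and 0.0537), and that of Fosb also in limma-voom (adjusted p = 0.0640).

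Among called genes with at least 5 CPM and no overlap between the groups, predicted genes left out, the largest fall was that of Fam167a (log2 fold change -2.34 ± 0.26), followed by the desmosome component Pkp1 (-2.10 ± 0.16), the organic anion transporter Slco4a1 (-1.94 ± 0.20), the Langerhans-cell lectin Cd207 (-1.92 ± 0.21) and the neuronal pentraxin Nptx1 (-1.89 ± 0.28). Hoxc13 fell by 1.82 ± 0.19 on the log2 scale. Pparg, the nuclear receptor that directs adipocyte differentiation, fell from 16.8 ± 2.46 to 4.89 ± 1.68 CPM. Tifab, Pcp4l1 and the cannabinoid receptor gene Cnr2 fell by 1.65, 1.58 and 1.51 on the log2 scale. Adjusted p values of these 10 genes lay between 0.000318 and 0.00287 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

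Of 15 circadian clock genes, 11 rose, 0 fell and 4 did not pass, and when adjusted over the list alone 13 were higher and 1 lower. Cry2, a repressor of the clock, rose from 19.8 ± 1.09 to 57.8 ± 2.04 CPM. The clock repressor genes Per2 and Per1 rose from 12.9 ± 1.43 to 37.0 ± 2.82 and from 21.6 ± 1.54 to 49.9 ± 4.15 CPM, and Bhlhe40 rose from 40.6 ± 2.49 to 135 ± 19.9 CPM. The list's median log2 fold change was 1.16, and camera, which compares a list with all other genes, called it higher (adjusted p = 1.06e-06). The value was adjusted p = 0.106 in camera with an estimated correlation. That correlation among the members was -0.0174, below the preset 0.01, so a higher correlation does not account for the larger value. After removal of the GC and length trends 10 of the 15 were called higher. Between 9 and 11 were called higher when 1 library was left out.

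**Figure D2:**
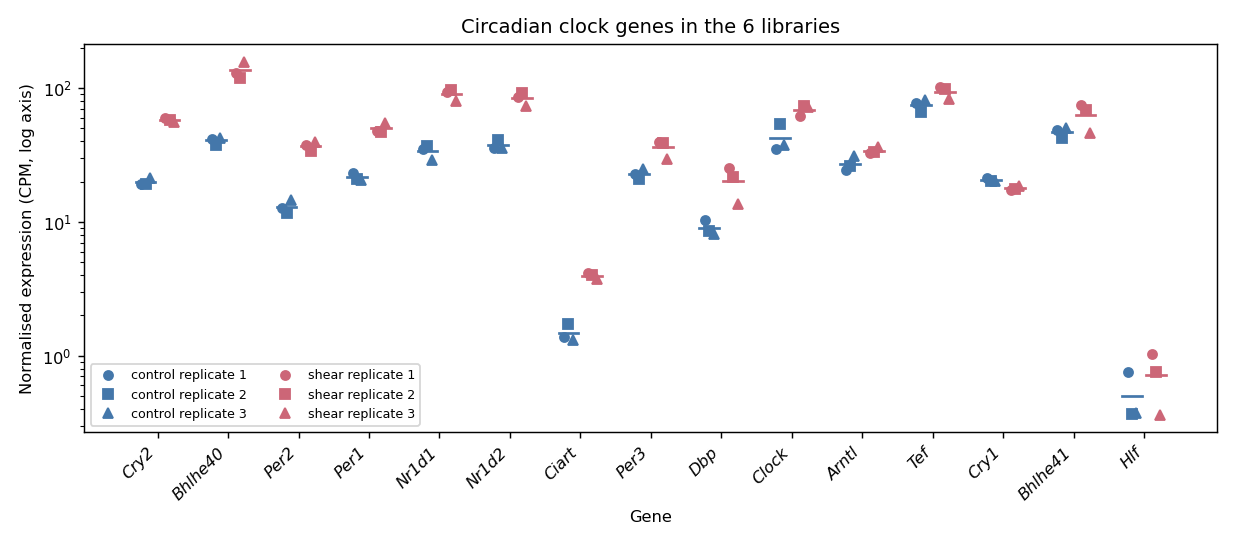
Normalised expression (CPM, log axis) of the 15 tested circadian clock genes in each control (blue) and shear (red) library, with symbols for replicates 1 to 3 and a line at each group mean. Bhlhe40 lay at 40.6 CPM in controls and 135 CPM after shear.

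Of 25 cell cycle genes, 17 fell, 1 rose and 7 did not pass, and 18 were lower and 2 higher when adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, fell from 64.3 ± 4.37 to 29.5 ± 3.71 CPM. The mitotic kinase genes Aurka and Plk1 fell by 1.12 ± 0.11 and 0.93 ± 0.09 on the log2 scale, and Mcm5, part of the replicative helicase, by 0.73 ± 0.07. The 1 gene that rose, named after its value was seen, was Cenpf (0.59 ± 0.19), which encodes a kinetochore protein, and its call was lost after the GC and length correction (edgeR adjusted p = 0.270) and without control replicate 1 (0.0999), control replicate 3 (0.104), shear replicate 2 (0.150) or shear replicate 3 (0.0788). Camera called the list lower at a median log2 fold change of -0.45 (adjusted p = 0.000103), and the value was adjusted p = 0.689 with an estimated correlation.

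Of 18 p53 and apoptosis genes, 6 rose and 2 fell, the same numbers as when adjusted over the list alone. The stress gene Gadd45a rose from 13.1 ± 2.34 to 45.7 ± 5.40 CPM, the death receptor gene Fas rose by 0.95 ± 0.11 on the log2 scale, and the anti-apoptotic gene Bcl2l1 fell by 0.43 ± 0.08. Without control replicate 1 the counts were 3 and 1, and without shear replicate 3 they were 7 and 5. Camera did not call the list (adjusted p = 0.347).

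Of 23 immediate-early response genes, 8 rose and 0 fell, as when adjusted over the list alone. Besides Egr3, Fosb and the Nr4a genes these included Ier5 (log2 fold change 0.68 ± 0.09). Camera called the list higher (median 0.35, adjusted p = 0.0464), with adjusted p = 0.745 with an estimated correlation. Shear replicate 3 held higher values of many members than the other shear libraries. Without it 8 genes were higher and 8 lower, the median was 0.05 and camera's adjusted p was 0.581, and without control replicate 1 that value was 0.0651. The list held 5 higher genes without control replicate 1 or control replicate 2 and with no filter on low counts. Fos, an AP-1 subunit named after its value was seen, had a log2 fold change of -0.81 ± 0.30 (edgeR adjusted p = 0.0858), and of -1.23 without shear replicate 3 (0.000656).

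**Figure D3:**
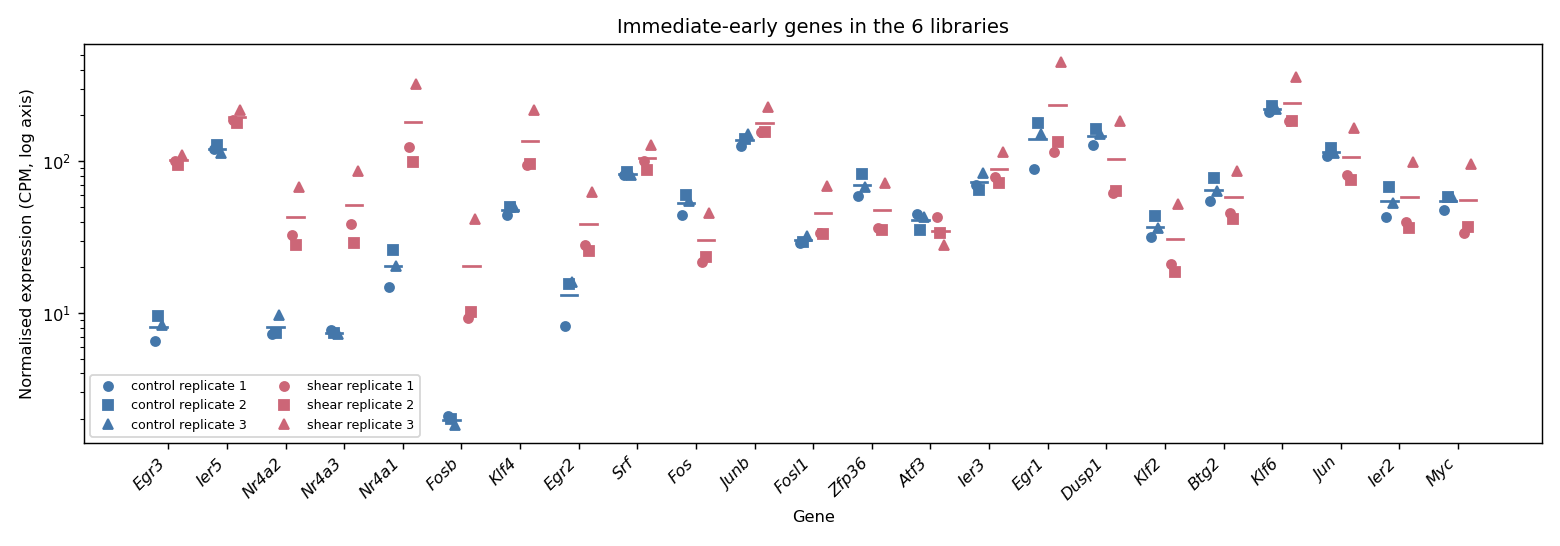
Normalised expression (CPM, log axis) of the 23 tested immediate-early genes in each control (blue) and shear (red) library, with symbols for replicates 1 to 3 and a line at each group mean. Egr3 rose to 101 ± 7.62 CPM with close shear libraries, while the shear value of Nr4a1, 181 ± 121 CPM, was spread by replicate 3.

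In the cartilage matrix and chondrocyte identity list, 4 of 12 tested genes rose and 1 fell, as when adjusted over the list alone, and camera did not call it (adjusted p = 0.551). Col11a1, a fibrillar collagen of cartilage, rose from 198 ± 7.21 to 277 ± 15.1 CPM. Sox9 on chromosome 11 (112782210 to 112787757) had a log2 fold change of -0.37 ± 0.09 (edgeR adjusted p = 0.0158). Its adjusted p was 0.0679, 0.0584 and 0.0543 without control replicate 1, control replicate 2 and shear replicate 2. Col2a1, the main cartilage collagen, stood at 78.0 ± 20.5 and 47.6 ± 13.3 CPM (log2 fold change -0.71 ± 0.27, edgeR adjusted p = 0.0881), and Acan, which encodes aggrecan, at 15.2 ± 4.70 and 8.78 ± 2.93 CPM (-0.80 ± 0.31, 0.0908). Neither passed the test with all libraries. Col2a1 passed without control replicate 3 (edgeR adjusted p = 0.0461), and Acan without control replicate 3 (0.0492) or shear replicate 3 (0.0341). DESeq2 called both (adjusted p = 0.00811 and 0.0204). Without control replicate 1, and likewise without shear replicate 2, the list held 2 higher and 0 lower genes, and without control replicate 3 it held 2 higher and 3 lower.

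Among 12 hypertrophy genes 3 rose and 2 fell, as when adjusted over the list alone, and camera did not call the list (adjusted p = 0.946). Sp7 and Runx2, transcription factors of hypertrophic cartilage and bone, fell by 1.21 ± 0.15 and 0.37 ± 0.08 on the log2 scale. Vegfa, the vascular growth factor, rose by 1.07 ± 0.21, a call lost without control replicate 1 (edgeR adjusted p = 0.0521). Without control replicate 1 the list held 0 higher genes, and without shear replicate 1, without shear replicate 2 or after the GC and length correction it held 1. The collagenase gene Mmp13 rose from 100.2 ± 26.9 to 196 ± 51.2 CPM (0.96 ± 0.26, edgeR adjusted p = 0.0344). That call was lost after the correction (0.108) and without control replicate 1 (0.106), control replicate 2 (0.0795), shear replicate 1 (0.0721) or shear replicate 2 (0.0875).

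Of 16 matrix-degrading proteases, 5 rose and 1 fell, and 7 were higher and 2 lower when adjusted over the list alone. Adamts5 on chromosome 16 (85858157 to 85901125) rose by 1.22 ± 0.08 on the log2 scale (edgeR's quasi-likelihood test, adjusted p = 0.000165), Adamts9 by 0.65 ± 0.12 and the gelatinase gene Mmp2 by 0.35 ± 0.08, the last with an adjusted p of 0.0534 without control replicate 3. In camera the list was higher (median 0.31, adjusted p = 0.0464), with adjusted p = 0.745 with an estimated correlation. Camera's call was lost without control replicate 2 (adjusted p = 0.0810), control replicate 3 (0.0651), shear replicate 1 (0.0578) or shear replicate 3 (0.0891), and without control replicate 1 only 3 genes were higher.

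Of 24 NF-kB and inflammatory mediators, 5 rose and 1 fell, and 2 were higher and 1 lower when adjusted over the list alone. Nfkbiz, an atypical IkB protein, rose from 19.1 ± 3.07 to 44.4 ± 4.38 CPM. Ptgs2, the inducible cyclooxygenase, rose by 2.08 ± 0.48 on the log2 scale, with shear libraries spread at 382 ± 265 CPM. Its edgeR adjusted p was 0.0831, 0.0678 and 0.0544 without control replicates 1, 2 and 3, and 0.0623 after the GC and length correction. The chemokine gene Ccl20 fell from 3.20 ± 1.58 to 0.950 ± 0.485 CPM, with edgeR adjusted p of 0.0683, 0.0867, 0.0716 and 0.102 without control replicate 1, control replicate 3, shear replicate 1 and shear replicate 2. Camera did not call the list (adjusted p = 0.120), which held 1 higher and 0 lower genes without control replicate 1, 2 and 4 without control replicate 2, 3 and 0 without either of shear replicates 1 and 2, and 2 and 1 after the GC and length correction. Without control replicate 3 camera called it higher (adjusted p = 0.0128), with 6 higher and 0 lower genes. With no filter on low counts 1 gene was higher and 1 lower, in DESeq2 8 were higher and 3 lower, and on log2(FPKM + 1) with no filter 3 were higher.

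Of 12 fibroblast and synovial-lining markers, 4 rose and 0 fell, and 5 were higher when adjusted over the list alone. Postn, an extracellular matrix protein of fibroblasts, rose from 360 ± 44.7 to 1049 ± 46.2 CPM, and the proteoglycan genes Dcn and Lum rose by 1.47 ± 0.27 and 1.30 ± 0.26 on the log2 scale, with an edgeR adjusted p of 0.0897 for Dcn after the GC and length correction. Col1a1, the collagen of fibroblasts and bone, was at 10417 ± 885 CPM in controls and 10680 ± 603 CPM after shear (0.04 ± 0.09, edgeR adjusted p = 0.789), far above Col2a1 in both groups. Tested as a set with camera, the list was higher (median 0.32, adjusted p = 0.0438), with adjusted p = 0.689 with an estimated correlation.

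Of 19 mechanosensitive channels, integrins and their partners, 7 rose and 2 fell, and 8 were higher and 2 lower when adjusted over the list alone. The gap junction gene Gja1 fell from 438 ± 7.38 to 312 ± 3.48 CPM, while the collagen receptor genes Itga1 and Ddr2 rose by 0.74 ± 0.10 and 0.49 ± 0.08 on the log2 scale. Piezo1, a mechanically gated channel, fell by 0.20 ± 0.06 (edgeR adjusted p = 0.0385), with an adjusted p of 0.0798 after the GC and length correction and of 0.0771 to 0.147 in the 5 fits that left out 1 library other than shear replicate 3. Trpv4, a calcium channel that responds to osmotic and mechanical load, was at 7.03 ± 1.27 and 5.34 ± 1.02 CPM (-0.40 ± 0.19, edgeR adjusted p = 0.153). Camera did not call the list (adjusted p = 0.347). It held 4 higher and 1 lower genes without control replicate 1, without shear replicate 2, and after the GC and length correction.

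Of 21 YAP/TAZ target genes, 9 rose and 4 fell, and 10 were higher and 4 lower when adjusted over the list alone. Nt5e, Rbms3 and Asap1 rose by 0.86 ± 0.14, 0.81 ± 0.11 and 0.42 ± 0.06 on the log2 scale, Rbms3 with an edgeR adjusted p of 0.0756 after the GC and length correction. Dock5 fell by 0.51 ± 0.06. Amotl2, a target that binds YAP, named after its value was seen, fell by 1.36 ± 0.34 (edgeR adjusted p = 0.0283), with an adjusted p of 0.0603 to 0.0872 in the 5 fits that left out 1 library other than shear replicate 3 and of 0.0733 after the correction. Camera did not call the list (adjusted p = 0.296). It held 3 higher and 2 lower genes without control replicate 1, 5 and 2 without control replicate 3, 2 lower without either of shear replicates 1 and 2, and 10 and 7 without shear replicate 3. Of 19 MRTF/SRF cytoskeletal genes only Fhl2 rose (0.61 ± 0.16), and none did when adjusted over the list alone. Its edgeR adjusted p was 0.102, 0.0772 and 0.0687 without control replicates 1, 2 and 3. Without shear replicate 3, 10 of the 19 were lower and the median log2 fold change was -0.28 in place of 0.01. Camera's adjusted p for the 19 genes was 0.979, and without shear replicate 3 it called them lower (adjusted p = 0.0182). Of 11 primary cilium and hedgehog genes, 4 rose and 1 fell, as when adjusted over the list alone, with Arl13b, a ciliary GTPase, at 0.49 ± 0.10 (edgeR adjusted p = 0.0591 after the correction) and the hedgehog repressor gene Sufu at -0.35 ± 0.07. Camera's adjusted p was 0.315, and 1 gene was higher without control replicate 1, without shear replicate 2 and after the correction, and 2 without control replicate 2.

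**Figure D4:**
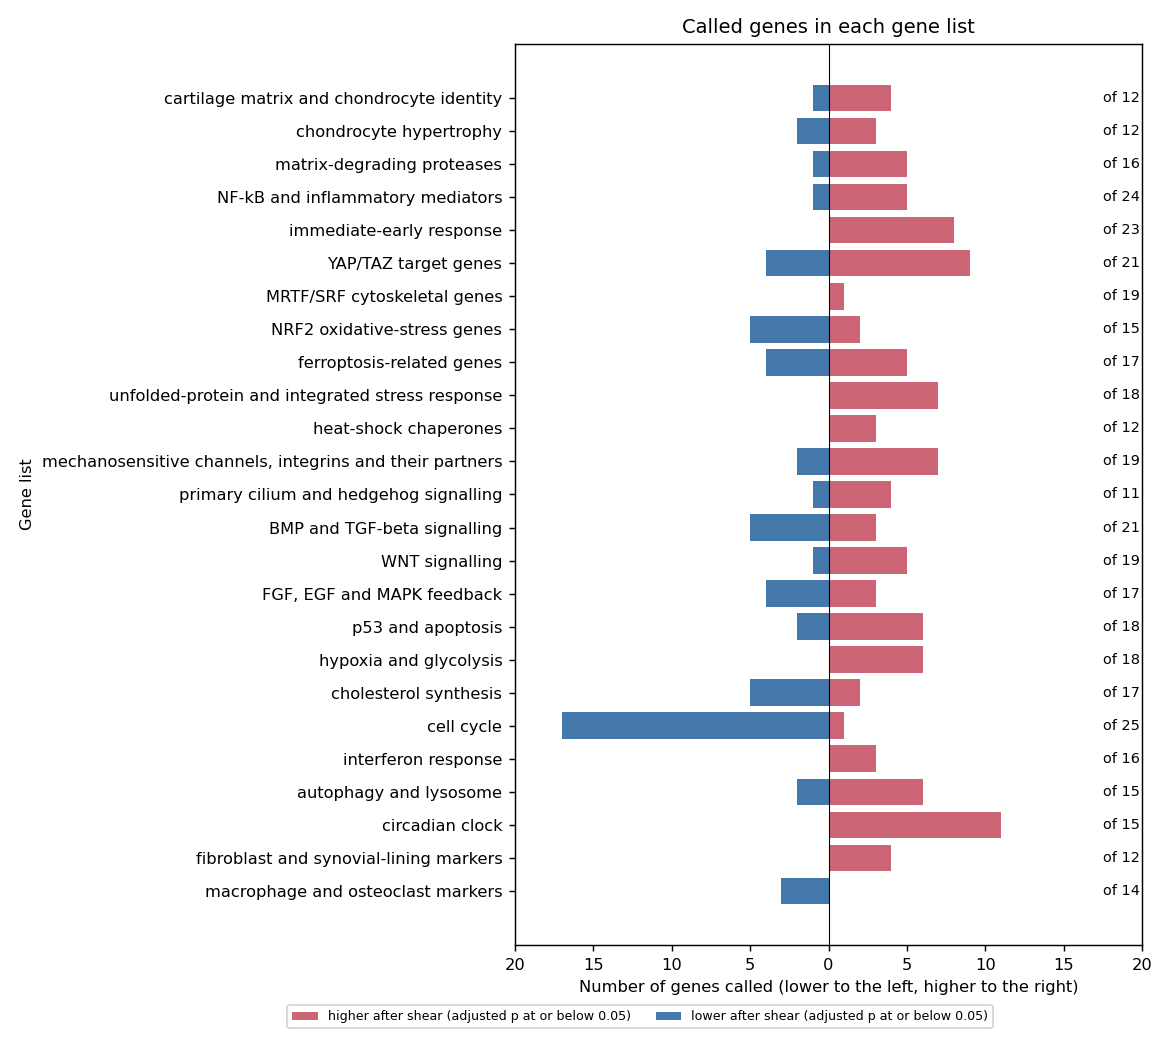
Number of genes called higher (red, to the right) or lower (blue, to the left) after shear in each of the 25 gene lists with at least 5 tested members (y axis, list; x axis, number of genes; the number tested stands at the right). The cell cycle list held 17 lower genes of 25 and the circadian clock list 11 higher genes of 15.

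Of 18 unfolded-protein and integrated stress response genes, 7 rose and 0 fell, and 8 were higher when adjusted over the list alone. Trib3, a pseudokinase induced by ATF4, rose from 3.52 ± 0.534 to 11.7 ± 1.39 CPM. Herpud1, a component of endoplasmic reticulum degradation, rose by 0.74 ± 0.07 on the log2 scale, and the endoplasmic reticulum chaperone gene Hsp90b1 by 0.76 ± 0.08. Camera called the list higher (median 0.15, adjusted p = 0.0234), with adjusted p = 0.689 with an estimated correlation. Of 12 heat-shock chaperones, 3 rose and 0 fell by either adjustment, that over all genes and that adjusted over the list alone. Hspa4l rose by 0.95 ± 0.08 and Hsp90aa1 by 0.80 ± 0.15, camera's adjusted p was 0.247, and without shear replicate 3 there were 3 higher and 2 lower genes.

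Of 15 NRF2 oxidative-stress genes, 5 fell and 2 rose, and 7 were lower and 2 higher when adjusted over the list alone. Hmox1, which encodes the haem-degrading enzyme, fell from 2233 ± 90.4 to 1437 ± 115 CPM, and Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, fell by 0.45 ± 0.07 and 0.36 ± 0.06 on the log2 scale. Osgin1 rose by 0.65 ± 0.08. Camera called the list lower (median -0.25, adjusted p = 0.0464), with adjusted p = 0.689 with an estimated correlation, and its call was lost without control replicate 1 (adjusted p = 0.0523), control replicate 3 (0.0764) or shear replicate 2 (0.0857) and after the GC and length correction (0.0754). Of 17 ferroptosis-related genes, 5 rose and 4 fell, and 5 of each were found when adjusted over the list alone. Acsl4, which activates polyunsaturated fatty acids, rose by 0.85 ± 0.07, Chac1, which degrades glutathione, by 1.41 ± 0.24 and the transferrin receptor gene Tfrc by 0.50 ± 0.09, the last with an edgeR adjusted p of 0.361 after the correction. Camera's adjusted p was 0.881. The list held 3 higher and 2 lower genes without control replicate 1, and 2 higher and 4 lower after the correction.

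Of 18 hypoxia and glycolysis genes, 6 rose and 0 fell, as when adjusted over the list alone. Besides Vegfa, the hexokinase gene Hk2 rose by 1.03 ± 0.12 and the mitophagy receptor gene Bnip3 by 0.64 ± 0.11 on the log2 scale. By camera the genes were higher as a set (median 0.35, adjusted p = 0.0477), with adjusted p = 0.745 with an estimated correlation, and the call was lost without control replicate 2 (adjusted p = 0.158) or shear replicate 1 (0.109). Of 17 cholesterol synthesis genes, 5 fell and 2 rose, and 6 and 2 when adjusted over the list alone. Sqle, a rate-controlling enzyme of the pathway, fell by 0.60 ± 0.07 and Insig1, which holds back sterol synthesis, rose by 1.03 ± 0.08. Camera's adjusted p was 0.178, and 3 genes were lower without control replicate 1, control replicate 2, shear replicate 1 or shear replicate 2. Of 15 autophagy and lysosome genes, 6 rose and 2 fell, and 6 and 3 when adjusted over the list alone. Fnip1, a partner of folliculin, rose by 1.41 ± 0.13, Lamp2 by 0.47 ± 0.07 and the lysosomal transcription factor gene Tfeb fell by 0.73 ± 0.12. Lamp2 had a log2 fold change of 0.02 and an edgeR adjusted p of 0.840 after the GC and length correction, and camera's adjusted p for the list was 0.347. Without control replicate 1, control replicate 3, shear replicate 1 or shear replicate 2 the list held 3 higher genes. Of 16 interferon response genes, 3 rose and 0 fell, as when adjusted over the list alone, with Ifi44 at 1.61 ± 0.17 and the RNA sensor gene Ifih1 at 0.97 ± 0.14. Camera called this list higher (median 0.69, adjusted p = 0.0234), with adjusted p = 0.745 with an estimated correlation, and 6 genes were higher without control replicate 3.

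Of 21 BMP and TGF-beta genes, 3 rose and 5 fell, and 3 and 6 when adjusted over the list alone. The BMP-induced genes Id1 and Id3 fell from 55.8 ± 3.21 to 23.5 ± 3.06 and from 339 ± 4.16 to 206 ± 12.1 CPM, while Skil, a SMAD corepressor, rose from 77.1 ± 4.34 to 171 ± 6.23 CPM and the BMP antagonist gene Grem1 rose by 0.55 ± 0.11 on the log2 scale. Of 19 WNT genes, 5 rose and 1 fell, as when adjusted over the list alone. The secreted WNT regulators Dkk2 and Rspo3 rose by 0.94 ± 0.11 and 0.92 ± 0.14, and the ligand gene Wnt4 fell by 1.41 ± 0.27. Of 17 FGF, EGF and MAPK feedback genes, 3 rose and 4 fell, and 5 and 4 when adjusted over the list alone. Fgf18, a growth factor for cartilage, fell by 1.27 ± 0.18, its receptor gene Fgfr3 by 0.81 ± 0.17 and the ERK phosphatase gene Dusp4 by 1.29 ± 0.19. Camera called none of these lists (adjusted p = 0.794, 0.163 and 0.422). Without control replicate 1 the BMP and TGF-beta list held 2 higher and 2 lower genes and the FGF list 1 and 3, as without control replicate 2, the BMP and TGF-beta list held 3 lower genes without control replicate 3 or shear replicate 2, and without shear replicate 3 the former held 3 and 9. The WNT list held 2 higher genes without control replicate 2 and 3 without control replicate 1, control replicate 3 or shear replicate 2.

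Of 14 macrophage and osteoclast markers, 3 fell and 0 rose, and 0 passed when adjusted over the list alone. Lyz2, a macrophage lysozyme named after its value was seen, was at 5948 ± 726 CPM in controls and 4179 ± 1102 CPM after shear (log2 fold change -0.51 ± 0.19, edgeR adjusted p = 0.0829, and 0.0109 without shear replicate 1). Csf1r and Tyrobp, a receptor and an adaptor of macrophages, had log2 fold changes of -0.85 ± 0.26 and -0.67 ± 0.19 (edgeR adjusted p = 0.0497 and 0.0390). Their calls were lost without control replicates 1, 2 and 3 and shear replicate 2 (edgeR adjusted p = 0.136, 0.107, 0.0918 and 0.103 for Csf1r, and 0.126, 0.0673, 0.0918 and 0.122 for Tyrobp) and after the GC and length correction (0.0597 and 0.112). Camera called the list lower (median -0.45, adjusted p = 0.0464), with adjusted p = 0.745 with an estimated correlation, and the call was lost without control replicate 1 (adjusted p = 0.0755), control replicate 3 (0.0573) or shear replicate 3 (0.308) and after the GC and length correction (0.0570). The count of lower genes was 0 without control replicate 2, control replicate 3 or shear replicate 2, 1 without control replicate 1 and after the correction, 5 without shear replicate 3 and 7 without shear replicate 1, and DESeq2 called 7 of 15 lower.

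The remaining marker lists had fewer than 5 tested members after the main filter and no set test there. With no filter on low counts camera called the endothelial list lower (9 tested, median -1.08, adjusted p = 0.0447). It did not call the osteoblast, skeletal-muscle, adipocyte and erythroid lists (camera adjusted p = 0.307 to 0.459). Of 4 endothelial markers 3 fell, as when adjusted over the list alone, among them Kdr, from 3.05 ± 0.331 to 1.34 ± 0.511 CPM (edgeR adjusted p = 0.0216, and 0.0825 and 0.0662 without control replicate 1 and shear replicate 2). No endothelial marker passed without control replicate 1 or shear replicate 2, and 1 passed without control replicate 2 or control replicate 3. Of 8 adipocyte markers only 3 were expressed highly enough to be tested, too few to tell of a change in adipocyte genes. Of these 3 Pparg fell, and 2 were lower when adjusted over the list alone. Lpl, which encodes lipoprotein lipase, was at 680 ± 39.4 and 354 ± 145 CPM (-0.94 ± 0.31, edgeR adjusted p = 0.0638), and passed without shear replicate 1 (0.0457), without shear replicate 3 (0.00103) and after the GC and length correction (0.0490). Of 4 osteoblast markers only Sp7 fell, and of 4 skeletal-muscle markers 0 passed, with the same counts when adjusted over the list alone. No erythroid marker was expressed highly enough to pass the main filter.

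The other list members that the naming rule took are given here with their log2 fold changes. Dnajb9 (0.60 ± 0.08), Pfkfb3 (0.57 ± 0.13), Msmo1 (-0.40 ± 0.07), Ifit2 (0.80 ± 0.12) and Wipi1 (0.31 ± 0.06) passed the test in every fit that left out 1 library. So did Pkd2 (0.30 ± 0.06) and Spred2 (0.55 ± 0.08), whose calls were lost after the GC and length correction (edgeR adjusted p = 0.0648 and 0.168). Each of 15 others passed with all libraries and lost its call without at least 1 of them. Adamts1 (0.83 ± 0.17) lost it without control replicate 1 (edgeR adjusted p = 0.0511) and Bbc3 (0.93 ± 0.20) without control replicate 3 (0.0512). Sox6 (0.68 ± 0.17) lost it without shear replicate 2 (edgeR adjusted p = 0.0725) and after the correction (0.212), and Stard4 (0.35 ± 0.08) without control replicate 1 (0.0546) and after the correction (0.129). Ift80 (0.43 ± 0.10) lost it without control replicate 1 (edgeR adjusted p = 0.0622) or shear replicate 2 (0.0542) and after the correction (0.304), and Pdgfra (0.74 ± 0.17) without the same libraries (0.0582 and 0.0662). For Nkd2 (0.34 ± 0.09) the libraries were control replicates 2 and 3 and shear replicate 1, with edgeR adjusted p of 0.0597 to 0.0833. Atp6v0d2 (-0.99 ± 0.26) lost its call without control replicate 2, control replicate 3 or shear replicate 2 (edgeR adjusted p = 0.0554 to 0.0803). Its log2 fold changes were then -0.87, -0.944 and -1.113.

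Hapln1 (0.69 ± 0.20) lost its call without control replicates 1 or 3 or shear replicates 2 or 3 (edgeR adjusted p = 0.0602 to 0.0993) and after the correction (0.218). Spp1 (0.30 ± 0.08) lost it without control replicates 1 or 3 or shear replicates 1 or 2 (edgeR adjusted p = 0.0586 to 0.102) and after the correction (0.179). The call of Tnfaip6 (0.79 ± 0.24) was lost without any 1 of the controls (edgeR adjusted p = 0.105 to 0.124) and after the correction (0.131), and that of Dnajb1 (0.30 ± 0.09) without any 1 of the controls or shear replicate 2 (0.0539 to 0.127). Gli3 (0.37 ± 0.11) was not called without control replicates 1 or 2 or shear replicates 1 or 2 (edgeR adjusted p = 0.0641 to 0.110). Among endothelial markers, Erg (-1.08 ± 0.33) was called in 1 of the 6 such fits and not after the correction (edgeR adjusted p = 0.0618), and Vwf (-0.96 ± 0.30) also in 1 of the 6. Of 11 rule-named members that did not pass, Filip1l (0.54 ± 0.26), Myh9 (-0.14 ± 0.07), Actb (-0.18 ± 0.11), Irf1 (-0.69 ± 0.23) and C1qb (-0.61 ± 0.20) passed when 1 shear library was left out. Bag3 (0.11 ± 0.06) passed after the correction (edgeR adjusted p = 0.0246). Ibsp (0.14 ± 0.66), Alpl (0.00 ± 0.15), Egfl7 (-0.40 ± 0.31), Des (-1.38 ± 0.66) and Fabp4 (-0.26 ± 0.15) passed in none of these fits.

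Some calls also depended on other settings. With no filter on low counts, 9 more genes besides Fosb and Edn1 lost theirs, namely Mmp13, Ptgs2, Amotl2, Piezo1, Csf1r, Tyrobp, Dusp6, Tnfaip6 and Erg (edgeR adjusted p = 0.0506 to 0.112). Tnfaip6 was not called in limma-voom (adjusted p = 0.0608), Erg not in DESeq2 (0.0695) and Cenpf not with library totals in edgeR (0.0561). In limma on log2(FPKM + 1) Cenpf and Gli3 were not called (adjusted p = 0.0663 and 0.0565), nor on log2(FPKM + 0.1) (0.0738 and 0.0568), and without the FPKM filter Csf1r, Sox6, Hapln1, Tnfaip6, Dnajb1 and Vwf were not either (0.0551 to 0.0706). DESeq2 called Fos, Lyz2, Cd68, Lpl, Irf1 and C1qb, which edgeR did not (adjusted p = 0.00254 to 0.0238). With at least 1 CPM in 3 libraries camera no longer called the matrix-degrading protease, immediate-early, NRF2, hypoxia, fibroblast and macrophage lists (adjusted p = 0.0537 to 0.0618), and with library totals it did not call the macrophage list (0.0584). Among list counts, 1 macrophage marker was lower and 3 ferroptosis genes were higher with no filter on low counts, 5 interferon genes were higher in DESeq2, and on log2(FPKM + 1) with no filter 1 cartilage gene and 3 WNT genes were higher. The count of higher cell cycle genes, 1 with all libraries, lay between 0 and 3 in the other fits named here, and was 4 with the replicate number as a block.

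The counting strand was not given, so whether reads of overlapping genes were told apart is not known. Overlap was taken over whole gene spans, introns included and on either strand, and overlap of exons was not tested. Of the 142 genes named, 49 overlap another annotated gene, among them Cdc20 with Elovl1, Aurka with Cstf1, Itga1 with Pelo, Piezo1 with Ctu2 and Bcl2l1 with Cox4i2. Of the 114 genes named by the rule that passed the test, 86 passed in every fit that left out 1 library and 28 did not. Most were taken for a large change or a small p in these same libraries, so this share does not stand for all calls. Of all 3957 changed genes, 53.2% were called again without control replicate 1 and 57.1% without shear replicate 2.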

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

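Of the tests reported here, those with the GC and length correction were chosen only after the data were seen. The 3957 changed genes became 3760 to 4131 with other factors, count filters, DESeq2 or limma-voom, and 3563 to 3987 on the FPKM table, where 83.6% to 90.4% of the 3957 were called in the same direction. The share of higher genes among the calls was 53.1%, and 46.9% with log2(FPKM + 1) and 46.4% after the correction. Genes changed at least 2-fold numbered 528, 378 with log2(FPKM + 0.1), 150 with log2(FPKM + 1) and 148 without its filter; the first and second of these FPKM fits differ in the pseudocount alone. Without 1 library the calls ran from 2127 (without control replicate 1) to 5153 (without shear replicate 3), with 2578 without control replicate 3 and 2285 without shear replicate 2, higher genes from 1223 to 2544, lower genes from 904 to 2609, and 2-fold genes from 345 to 638; each such fit has fewer samples, and between 53.2% and 95.0% of the 3957 were called again in the same direction. Lists called higher and lower by camera, 7 and 3, became 3 and 1 with at least 1 CPM in 3 libraries, 0 and 0 with an estimated correlation (camera, 1 list at an unadjusted p of 0.05 or less), 7 and 1 after the correction, and 5 to 7 higher and 1 to 3 lower without 1 library; the cause was not tested. Fry, which tests against no change, called 7 higher and 2 lower, 6 of them lists that camera called in the same direction; it added the p53, WNT and primary cilium lists and left out the immediate-early, hypoxia, interferon and macrophage lists. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.15, -0.05 and -0.08). With the replicate number as a block 3591 genes were called, 1950 higher, 1641 lower and 523 at least 2-fold. Of the named genes 5 were then not called, namely Mmp13, Piezo1, Gli3, Erg and Vwf (edgeR adjusted p = 0.0507 to 0.0819). Calls were gained by 4 others, Fos, Lyz2, Cd68 and C1qb (edgeR adjusted p = 0.0145 to 0.0471), and 8 macrophage markers were lower in place of 3. Of 142 named genes, 22 lost and 2 gained a call after the correction, and 1 turned over. Among genes that did not pass the test, Ptprc had a log2 fold change of -0.12 after the correction. Without 1 library Col1a1 ran from -0.032 to 0.081, Adgre1 from -0.22 to 0.68, Ibsp from -0.29 to 0.946 and Alpl from -0.087 to 0.166. Alpl, at 0.001 with all libraries, was at -0.013 with upper-quartile factors, -0.008 with library totals, -0.001 with log2(FPKM + 1), filtered or not, and 0.000 with log2(FPKM + 0.1). The cause was not tested. Low counts limit genes such as Ibsp, at 0.533 CPM in controls and 0.584 CPM after shear.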

Other observations

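Tests chosen only after a result was seen were those of the gene ontology terms, the added gene lists, the GC and length correction, the marker ratios of macrophages, the spread among cell cycle genes and the genes called again, and so were the bootstrap spread used for list medians and the comparison of the FOXO list with other splits, which moved the outcome of both FOXO tests to undecided; an earlier, unpaired form of the bootstrap also left the clock test undecided, and the paired form did not. Among 1965 gene ontology terms taken from the count table's annotation, camera called 0 higher and 2 lower, with 99 higher and 96 lower at an unadjusted p of 0.05 or less. In "ATP hydrolysis coupled proton transport", 12 of 21 genes fell and 0 rose (median log2 fold change -0.25, camera adjusted p = 0.00643), and in "proton-transporting ATPase activity, rotational mechanism" 9 of 16 fell and 0 rose (-0.27, 0.0271). The 2 terms share most of their members and are not separate results. Most members are subunits of the vacuolar proton pump, which acidifies lysosomes. The largest fall in both terms was that of Atp6v0d2 (-0.99), which is also on the list of macrophage and osteoclast markers, of which 3 of 14 fell. Neither was called after the GC and length correction (camera adjusted p = 0.0668 and 0.0676).

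With 10 splits of the libraries into 3 and 3, no share under 0.05 can be had. Every other split also mixes control and shear libraries in both groups. Differences between control and shear then widen the spread within its groups and hold down its calls, while part of that contrast remains. The other splits therefore give no measure of what would be called without shear, for genes or for lists. The real split was the 1 split with as many changed genes (3957, against 0 in the highest other), higher genes (2102 against 0), lower genes (1855 against 0) and genes changed at least 2-fold (528 against 0). At an unadjusted p of 0.05 edgeR's quasi-likelihood test gave 5633 genes in the real split and 52 to 602 in the others. For gene lists, camera called 7 higher and 3 lower, and up to 10 in 1 direction in another split. Thus 5 splits reached 7 and all 10 splits reached 3. Of the 25 lists, the circadian clock was the 1 list for which no other split gave a camera p as small (0.000295 against 4.23e-08 in the real split). For the cell cycle list another split gave 5.67e-09 against 8.21e-06, for interferon 3.53e-09 against 0.00361, for immediate-early genes 1.31e-08 against 0.0117, for the unfolded-protein response 4.21e-06 against 0.00374 and for macrophage markers 2.83e-10 against 0.0164.

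The trend with GC content was seen as a rank correlation of -0.36 between log2 fold change and transcript GC content over genes, which are not independent. A bias of single libraries is argued against by the slopes of log2 CPM on GC content. These were taken relative to the mean of the 6 libraries, so their signs are relative as well. They lay between 0.086 and 0.193 log2 per 10 percentage points in the 3 controls. In the 3 shear libraries they lay between -0.153 and -0.087, a gap of 0.1725. A bias of preparation shared by the shear libraries remains possible and could account for part of the calls, since the groups and any shared preparation are confounded. The slope of log2 fold change among the 1000 most abundant genes was 82.3% of that over all genes (-0.203 ± 0.016 SE and -0.247 ± 0.007 SE). A response to shear of AT-rich, long transcripts would give the same trend, so this value does not tell such a response from a bias. After the correction 63.1% of the changed genes were called again, which lies between the bounds set before and does not decide how much of the total is due to the trend (2497 genes; the other splits, which mix both groups, called 0 and so give no measure for this). The trend is argued against as the whole cause of the clock genes' rise, with a median of 0.894 after the correction (1.16 before; the bootstrap SD of its distance from 50% of the earlier value was 0.256, and 10 of the 15 genes were still called), and of the cell cycle genes' fall (-0.402, before -0.45), while the spread among cell cycle members narrowed to 72.1% of its size, which leaves open whether the rise of Cenpf, the 1 member called higher, came from it.

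A smaller share of macrophages may account for some or all of the lower macrophage markers, and the marker ratios do not decide it. Relative to the mean of the other markers 9 of 14 changed (limma, adjusted p of 0.05 or less), 3 higher and 6 lower. After the GC and length correction 2 were higher and 4 lower. Ptprc rose by 0.72 and Csf1r fell by 0.56 relative to the others, and Cd68 fell by 0.47. The markers thus did not all move alike, as those of 1 cell type would if only its share changed. The list, however, mixes macrophage and osteoclast markers, and each ratio also moves with the other markers. The GC and length trends are argued against as the whole cause of the lower markers, since the median was -0.35 after the correction and -0.45 before (bootstrap SD 0.0556 of its distance from 50% of the earlier value). Camera, however, no longer called the list (adjusted p = 0.0464 before and 0.0570 after), and Ptprc itself went from 0.31 to -0.12. Lyz2, at 5948 CPM in controls, was the most abundant of these markers, 0 of the 16 markers are in another of the 31 lists, and no sort of the cells is mentioned. Expression within macrophages was not tested.

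A list of 24 tested FOXO target genes, induced when growth-factor and AKT signalling is low, held 12 higher and 1 lower gene (Cat, -0.52), with a median of 0.52; Klf15 rose by 2.07, Klhl24 by 1.29 and Irs2 by 0.98. Lower growth-factor signalling under flow is a candidate explanation. Camera gave p = 0.00011, and p was 0.171 with an estimated correlation, so the test does not decide. Other splits gave camera p as small as 8.79e-06, but they mix both groups and so give no measure for this. The median was 0.276 after the GC and length correction, close to the bound of 50% of its value, and camera p was 9.38e-05, so that the trend is neither shown nor excluded as the cause. Serum and medium changes of the controls are not given and are confounded with shear. Of the other added lists, which partly hold genes already seen, camera in limma gave p = 0.000134 for cAMP and calcium CREB targets (8 higher and 1 lower of 14; 0.19 with an estimated correlation, and 6.03e-06 in another split), 0.507 for serum-response ERK targets (0 higher and 3 lower of 12, among them Dusp6, -1.08, whose call was lost after the correction and without any 1 library other than shear replicate 3) and 0.101 for glucocorticoid-induced genes (4 higher and 1 lower of 11; p = 0.0369 and a median of 0.69 after the correction, against 0.62 before).

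Shear replicate 3 alone is argued against as the source of the 8 immediate-early calls, because without it their median log2 fold change was 2.05 (2.59 with it) and 8 were called again, although 8 other members of the list were then lower and the list as a whole was not called (camera adjusted p = 0.581).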
